A study of Mus musculus with 6 samples.

How the data were processed

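The samples were 6 bulk RNA-seq libraries of about 1000 sorted CD133-positive, DAPI-negative cells from cultured mouse neocortex, 3 treated with DMSO and 3 with GSK2837808A. The deposited signal values, made by the authors, are normalised read counts in a single table with a value per gene and library. STAR and DESeq and the genome builds GRCm38 and mm10 are named in the submitters' processing notes, with no role, order or version. The read counter, the annotation release and strand settings are not given in the sources used here. Smart-seq2 does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

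The table held 118098 rows for 32285 genes, because each gene's value was repeated on every transcript row, and 1 row per gene was kept. Names came from the table. Of 128 genes without a name, 51 were named from a reference table and 77 kept their identifier. A symbol shared by several genes stayed with the gene of the higher mean, which left 32 duplicate symbols under their identifiers. Coordinates came from GENCODE vM21 on GRCm38, matched by identifier for 32235 genes. In every library 100% of the nonzero values were whole multiples of the smallest value within 0.01, so whole reads were recovered. The totals ran from 7187089 to 10224348 reads, and 2304 genes had 0 in every library. The 3 genes Gm42418, AY036118 and Gm26917, which overlap ribosomal RNA, took 21.1% ± 0.799 of reads in DMSO and 24.4% ± 1.54 in GSK libraries (SD, n = 3; two-sided exact permutation test, p = 0.1). The 20 most abundant genes took 25.0% ± 0.688 and 31.1% ± 1.65 (exact permutation p = 0.1), the smallest p that 3 against 3 allows. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 4.45 to 14.2, so none were counted as the same library.

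The main test was limma 3.58.1 in R 4.3.3, with trended and robust variance priors, on log2(value + 1). It ran on the 15073 genes with a mean of at least 10 over all 6 libraries, with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists of at least 5 tested members, 44 in all, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. camera with an estimated correlation and fry were run beside it. camera asks whether a list moves against the other genes, and fry whether its genes move one way against no change, so a call here means camera. A count adjusted over the list alone is given only where it differs by at least 1 and the list is called. Values per library were compared by two-sided exact permutation tests. Intervals of shares are 95% Wilson intervals.

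The test, the lists, the rule for named genes and most of the other settings below were chosen before the data were examined. Always named were Ldha, Ldhb, Slc16a1, Slc16a3, Vegfa, Prom1, Pax6, Sox2, Nes, Eomes, Neurog2, Tubb3, Mki67 and Cdkn1a. The 10 largest rises and 10 largest falls were taken among called protein coding genes with a mean of at least 100, no overlap between the groups and a symbol that is not a Gm number, Rik clone or pseudogene. Not all of these genes are printed. Each list gave up to 4 called members by smallest p, or up to 2 members where it was not called and had fewer than 3 called members. Asns and falling members of the ATF4 and neuron lists were named after their values were seen, as were the 6 radial glial markers that did not pass.

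On simulated counts with the genes' own means and dispersions and the libraries' own depths, 200 genes were changed and 15052 tested for the comparison of GSK with DMSO. Of the seeded changes, 74.0% were recovered at a log2 fold change of 1 and 98% at 2, and 10 of 179 calls were false. The simulated genes varied independently and few were changed, whereas 36.1% of the tested genes were called in the data. These shares therefore need not hold for the real calls. The alternatives were other pseudocounts, filters and scalings, array weights, a replicate block, each library left out in turn, a stricter threshold, a fold limit, protein coding genes alone, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A globin covariate, a correction for GC content and transcript length, a total without globin and ribosomal-RNA-overlapping genes, and a second estimator of array weights were added after the data were examined.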

Results

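Transcript levels were measured by bulk RNA sequencing in radial glial progenitors, the dividing stem cells that line the ventricle of the developing cortex, from the neocortex of wild-type mouse embryos at stage E10.5. Dissociated cortical cells were cultured and exposed for about 24 h to GSK2837808A, an inhibitor of lactate dehydrogenase, or to its solvent DMSO. Lactate dehydrogenase converts pyruvate to lactate and back. The labels state an inhibitor concentration of 100 mM, which is implausibly high for culture medium and was not verified, so the true dose is uncertain. About 1000 living cells carrying CD133, the product of Prom1, were sorted per sample and amplified with the Smart-seq2 protocol, which copies polyadenylated RNA. Each group held 3 libraries, named DMSO and GSK here. The DMSO libraries held 7837721, 10051625 and 9153671 reads and the GSK libraries 7187089, 10224348 and 8672179 reads, as recovered from the normalised values. Depth did not separate the groups (two-sided exact permutation test, p = 0.8, where 0.1 is the smallest p that 3 against 3 allows). Between 22879 and 25585 genes had a read in each library. No label says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

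The single comparison of the design asks how progenitors differ in gene expression when lactate production is inhibited. Progenitor and cell division genes were lower in GSK libraries, and genes of cholesterol synthesis, the integrated stress response, lysosomes and intermediate progenitors were higher. Globin genes of red blood cells showed some of the largest rises. Of 15073 genes tested, 5446 changed, 2563 upward and 2883 downward (limma on log2 values, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes numbered 759 upward and 1041 downward on the log2(value + 1) scale. The 3 GSK values lay wholly above or below the 3 DMSO values for 7121 genes, or 47.2%, against 10% by chance. The first principal component held 67.8% of the variance and separated the groups. Pearson correlations across genes were 0.971 to 0.984 within groups and 0.916 to 0.934 between them. Of 44 gene lists, 16 were higher and 8 lower against the other genes (camera with a preset correlation of 0.01, adjusted p below 0.05). None of these 24 calls held when the correlation between genes was estimated from the data, the smallest adjusted p then being 0.201. Many lists shared that adjusted value, so it does not rank them. Lists with an estimated correlation below the preset one, as Wnt targets (-0.017) and FGF and ERK targets (-0.0342), lost their call too. A high correlation is thus not the only reason for the loss, and the fit had only 4 residual degrees of freedom.

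**Figure D1:**
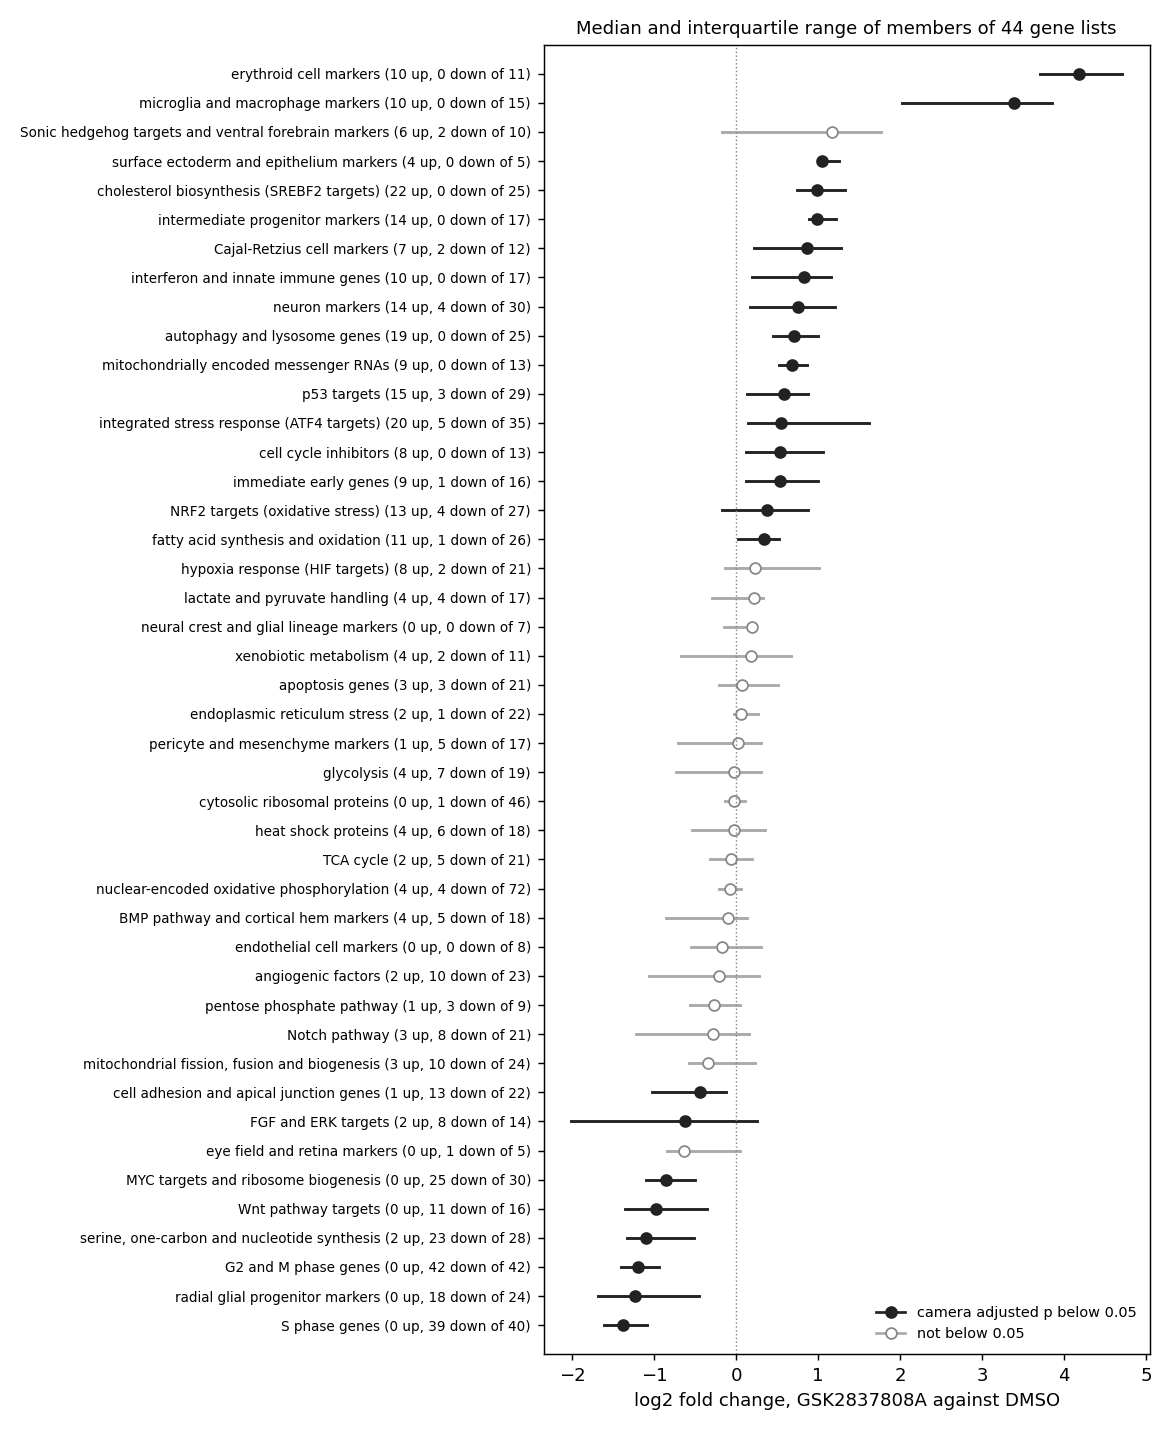
Each point is the median log2 fold change (GSK against DMSO, 3 libraries each) of a gene list's tested members, each line spans their interquartile range, and filled points mark lists with a camera adjusted p below 0.05. The erythroid list lies highest with a median of 4.18 and the S phase list lowest with a median of -1.38.

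Ldha, which encodes the lactate dehydrogenase subunit favoured in glycolytic cells (chromosome 7, 46841475 to 46855627, GRCm38), fell from 2339 ± 173 to 1384 ± 301 normalised reads (mean ± SD, n = 3 per group), a log2 fold change of -0.78 with a standard error of 0.15 (limma adjusted p = 0.000424). The lactate carrier gene Slc16a1 fell as well, by 0.64 on the log2 scale. Ldhb and the carrier gene Slc16a3 did not pass the test, with log2 fold changes of -0.18 and 0.29. Of the 19 glycolysis genes, 7 fell and 4 rose. Hk2, which encodes a hexokinase, had a log2 fold change of -2.19, and Pkm, which encodes pyruvate kinase, fell from 11003 ± 965 to 5989 ± 594. Pfkfb3 and Pgam1 fell with log2 fold changes of -0.94 and -0.74. The list as a whole did not differ from the other genes (camera adjusted p = 0.491), nor did the 17 genes of lactate and pyruvate handling (adjusted p = 0.596), of which 4 rose and 4 fell. Among these, Mpc1, part of the mitochondrial pyruvate carrier, rose with a log2 fold change of 0.73, and Pcx, which encodes pyruvate carboxylase, fell by 0.74 on the log2 scale.

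Radial glial genes fell broadly. Of 24 markers, 18 fell, 19 when adjusted over the list alone, and none rose, with a median log2 fold change of -1.23 (camera adjusted p = 1.93e-09; adjusted p = 0.201 with an estimated correlation). Prom1, the gene of the sort marker (chromosome 5, 43993620 to 44102032), fell from 1183 ± 72.2 to 591 ± 96.3 normalised reads. The progenitor transcription factor genes Pax6 and Sox2 had log2 fold changes of -1.38 and -1.46, and Nes, which encodes the filament protein nestin, of -1.24. Fabp7, a fatty acid binding protein gene of radial glia (chromosome 10, 57784881 to 57788450), fell from 2961 ± 301 to 219 ± 54.6 normalised reads, a log2 fold change of -3.78 with a standard error of 0.16 (limma adjusted p = 2.74e-12). Slc1a3, which encodes a glial glutamate transporter, and Hmga2 had log2 fold changes of -3.21 and -2.90. The 6 members that did not pass were Vim, Lhx2, Emx1, Emx2, Dmrt3 and Dmrta2.

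**Figure D2:**
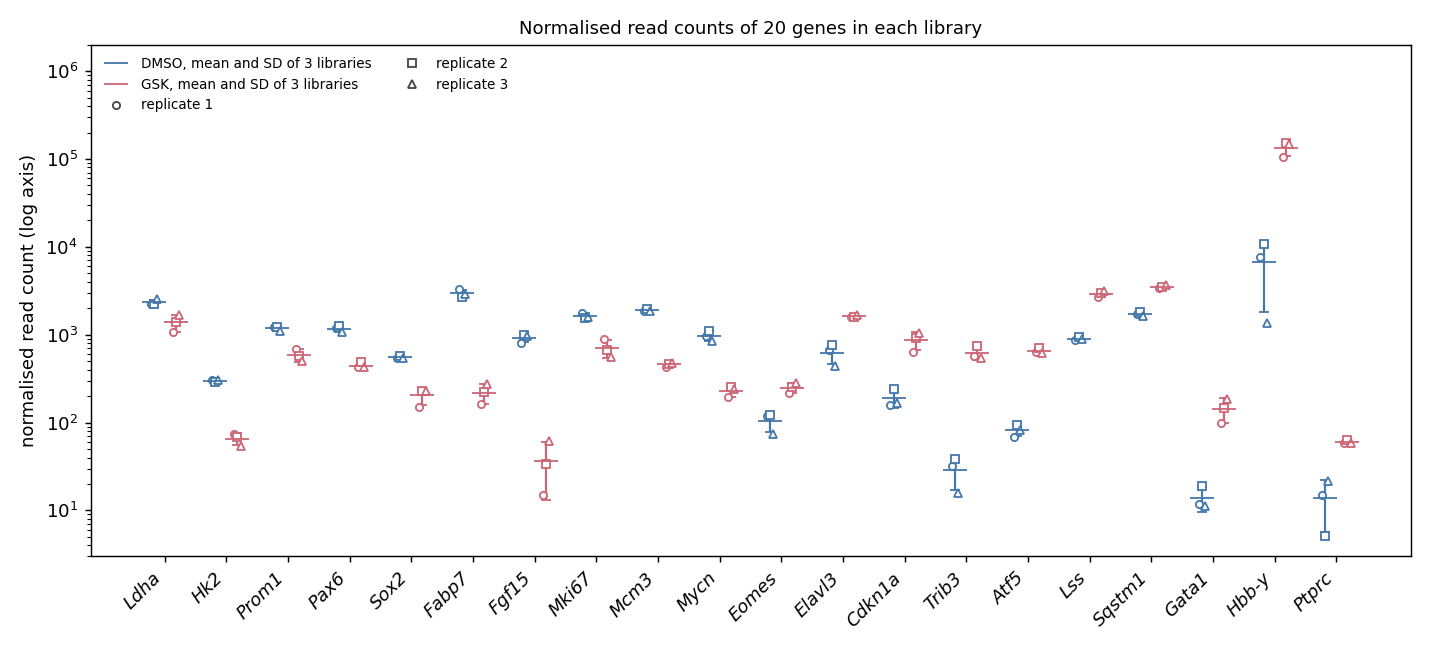
Normalised read counts on a log axis of 20 genes in the 3 DMSO and 3 GSK libraries, with bars for the mean and SD of each group and a symbol for each replicate. Fabp7 averaged 2961 in DMSO and 219 in GSK, and Trib3 averaged 28.8 in DMSO and 617 in GSK.

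Genes of cell division fell almost without exception. In the S phase list 39 of 40 genes fell, all 40 when adjusted over the list alone, with a median log2 fold change of -1.38 (camera adjusted p = 1.74e-22; adjusted p = 0.201 with an estimated correlation). Mcm3, part of the replicative helicase, fell from 1897 ± 74.6 to 459 ± 24.4 normalised reads, and Exo1, Uhrf1 and Pole had log2 fold changes of -2.16, -1.81 and -1.74. All 42 genes of the G2 and M phase list fell, with a median of -1.19 (camera adjusted p = 2.11e-21; adjusted p = 0.201 with an estimated correlation). Top2a, a DNA topoisomerase gene, fell from 5082 ± 278 to 1364 ± 199 normalised reads, and Mki67, a marker of cycling cells, from 1645 ± 125 to 704 ± 167. Cell cycle inhibitor genes moved the other way, with 8 of 13 higher and none lower (median 0.54, camera adjusted p = 0.00308; adjusted p = 0.201 with an estimated correlation). Cdkn1a, which encodes the inhibitor p21, rose from 191 ± 46.2 to 866 ± 203 normalised reads, and Cdkn1c rose with a log2 fold change of 1.08. Among 29 p53 targets 15 rose, including Cdkn1a, Btg2 and Sesn1, and 3 fell, including Gtse1 (camera adjusted p = 0.000461; adjusted p = 0.201 with an estimated correlation).

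Growth and nucleotide synthesis genes were lower. Of 30 MYC targets and ribosome biogenesis genes 25 fell, 26 when adjusted over the list alone (median -0.85, camera adjusted p = 1.85e-10; adjusted p = 0.201 with an estimated correlation), led by Mycn, which fell from 965 ± 124 to 229 ± 31.1 normalised reads, and by Srm, Rrp12 and Polr1b. Of 28 genes of serine, one-carbon and nucleotide synthesis 23 fell and 2 rose (median -1.09, camera adjusted p = 4.52e-09; adjusted p = 0.201 with an estimated correlation). Cad, which encodes the enzyme that starts pyrimidine synthesis, had a log2 fold change of -2.07, Shmt1 of -2.24, Rrm2 of -1.65 and Mthfd1 of -1.52. The 46 cytosolic ribosomal protein genes had a median of -0.02, and only Rpl10a passed the test, falling by 0.46. It lost its call without DMSO replicate 2, DMSO replicate 3 or GSK replicate 2 (highest adjusted p = 0.0995). Rps4x had a log2 fold change of 0.39 without passing (limma adjusted p = 0.0702), and was called higher with DESeq2 (0.0134), no filter on low values (0.0118), equal library totals (0.0468), array weights (2.88e-06) and without GSK replicate 1 (3.33e-05). The ribosomal protein list was not called (camera adjusted p = 0.973), but without GSK replicate 1 its median was 0.15 and the list was called higher (adjusted p = 0.0297), and with array weights its median was 0.17 (adjusted p = 0.0474), from an estimator that did not converge. With the gene by gene estimator it was not called.

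Signalling genes of the early cortex fell in part. Of 16 Wnt targets 11 fell and none rose, 1 rising when adjusted over the list alone (median -0.98, camera adjusted p = 1.69e-05; adjusted p = 0.201 with an estimated correlation), among them the cyclin gene Ccnd1 with a log2 fold change of -2.60, Tnfrsf19 with -2.25 and the feedback inhibitor gene Axin2 with -1.44. Of 14 FGF and ERK targets 8 fell and 2 rose (median -0.62, camera adjusted p = 0.0346; adjusted p = 0.201 with an estimated correlation), with Etv5, Fgfr3, Spry4 and Etv4 at log2 fold changes of -2.70, -2.26, -2.72 and -2.80. The FGF and ERK list was no longer called without GSK replicate 1 (adjusted p = 0.0725), with a mean of at least 100 (0.192), with equal library totals (0.0638) or with array weights (0.0743). Fgf15, which encodes a secreted growth factor (chromosome 7, 144896531 to 144900953), had the largest fall of all named genes, from 921 ± 101 to 36.8 ± 23.5 normalised reads, a log2 fold change of -4.82 with a standard error of 0.53 (limma adjusted p = 0.00202). Of 21 Notch pathway genes 8 fell, including Hes5, Lfng, Nrarp and Notch3, and 3 rose. The Notch list was not called (camera adjusted p = 0.0614). It was called lower with edgeR (adjusted p = 0.00247) and DESeq2 (0.0019), with no filter on low values (0.0406), a pseudocount of 10 (0.0455) or array weights (0.0479), and without GSK replicate 1 (0.0314). Tested against no change by fry, it was lower as well (adjusted p = 0.00297). Of 18 BMP pathway and cortical hem genes 5 fell, including Id3, Id1 and Bmp7, and 4 rose, including Msx2 (camera adjusted p = 0.451). In the cell adhesion and apical junction list 13 of 22 fell and 1 rose (median -0.44, camera adjusted p = 0.000242; adjusted p = 0.201 with an estimated correlation), led by the polarity gene Crb2, Lama1 and the cadherin gene Cdh2, with log2 fold changes of -2.27, -1.78 and -1.35.

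Targets of ATF4, the transcription factor of the integrated stress response, rose in majority. Of 35 genes 20 rose and 5 fell (median 0.54, camera adjusted p = 1.05e-06; adjusted p = 0.201 with an estimated correlation). Trib3, a pseudokinase gene (chromosome 2, 152337422 to 152344032), rose from 28.8 ± 11.7 to 617 ± 104 normalised reads, a log2 fold change of 4.45 with a standard error of 0.27 (limma adjusted p = 4.98e-08). Atf5 rose from 81.5 ± 11.9 to 654 ± 48.2 normalised reads. The amino acid transporter gene Slc7a3 rose with a log2 fold change of 3.74, Chac1 with 3.29, Ddit3 with 1.96 and the asparagine synthetase gene Asns with 1.70. The 5 that fell were Phgdh and Psat1, which encode enzymes of serine synthesis, Wars, and the transporter genes Slc7a1 and Slc38a2. Endoplasmic reticulum stress genes were not called as a list (2 of 22 higher, 1 lower, camera adjusted p = 0.335), although Herpud1 rose with a log2 fold change of 1.18. Heat shock protein genes went both ways (4 of 18 higher, 6 lower, camera adjusted p = 0.864), with Hspb8 and Dnajb4 higher and Fkbp4 and Hspd1 lower. Among 16 immediate early genes 9 rose and 1 fell (median 0.53, camera adjusted p = 0.00879; adjusted p = 0.201 with an estimated correlation), with log2 fold changes of 3.40 for Atf3, 1.10 for Junb and 0.82 for Egr1. Some genes belong to several lists. Atf3 is also in the ATF4 list, and Btg2 is in the immediate early, intermediate progenitor, cell cycle inhibitor and p53 lists. The 21 apoptosis genes were not called (3 higher, 3 lower, camera adjusted p = 0.596), with Bcl2l11 and Bcl2l1 higher and Bcl2 and Bid lower.

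Cholesterol synthesis genes rose together. Of 25 genes 22 rose and none fell (median 0.99, camera adjusted p = 1.23e-11; adjusted p = 0.201 with an estimated correlation). Lss, which encodes lanosterol synthase, rose from 903 ± 34.0 to 2924 ± 242 normalised reads, and Tm7sf2, Mvd and Msmo1 rose with log2 fold changes of 1.96, 1.76 and 1.57. Of 26 fatty acid genes 11 rose, 12 when adjusted over the list alone, and 1 fell (median 0.34, camera adjusted p = 0.00375; adjusted p = 0.219 with an estimated correlation), including the desaturase genes Scd1, Fads2 and Scd2. Autophagy and lysosome genes rose in 19 of 25 cases, 21 when adjusted over the list alone (median 0.70, camera adjusted p = 4.35e-08; adjusted p = 0.201 with an estimated correlation). The protease genes Ctsd and Ctsb rose with log2 fold changes of 1.27 and 1.00, and the autophagy receptor gene Sqstm1 with 1.04. Microglia and macrophage markers rose beside these lysosomal genes (median 3.39). Of 27 NRF2 targets 13 rose and 4 fell, 5 when adjusted over the list alone (median 0.37, camera adjusted p = 0.0216; adjusted p = 0.554 with an estimated correlation). Fth1, which encodes ferritin heavy chain, rose with a log2 fold change of 1.63 and Gpx1 with 1.47, and the glutathione transferase gene Gsta4 fell by 1.33. Of 11 xenobiotic metabolism genes 4 rose and 2 fell (camera adjusted p = 0.634). Cyp1a1 rose from 2.01 ± 1.94 to 60.0 ± 27.6 normalised reads, whereas Cyp1b1 fell by 1.68.

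Mitochondrially encoded messenger RNAs were higher for 9 of 13 genes, 11 when adjusted over the list alone (median 0.68, camera adjusted p = 7.8e-05; adjusted p = 0.243 with an estimated correlation). mt-Co1 rose from 12399 ± 2680 to 23662 ± 1395 normalised reads. The mitochondrial share of reads averaged 0.581% in DMSO libraries (0.519 to 0.697%) and 0.975% in GSK libraries (0.892 to 1.08%; n = 3 per group, two-sided exact permutation test, p = 0.1, the smallest possible). Nuclear genes of oxidative phosphorylation did not follow, with 4 of 72 higher and 4 lower (median -0.07, camera adjusted p = 0.491), although their list was called lower without GSK replicate 3 (adjusted p = 0.0376) and after a correction for GC content and length (adjusted p = 0.0404). The 21 TCA cycle genes (2 higher, 5 lower, camera adjusted p = 0.596), 9 pentose phosphate genes (1 higher, 3 lower, adjusted p = 0.413) and 24 genes of mitochondrial dynamics and biogenesis (3 higher, 10 lower, adjusted p = 0.276) were not called. Within them, Idh1 rose and Suclg2 fell, Tkt fell, and Nrf1 and Ppargc1a fell while Pink1 rose. Of 21 hypoxia genes 8 rose, including Bnip3, Bnip3l and Adm, and 2 fell. The hypoxia list was not called (camera adjusted p = 0.0787), but it was called higher without GSK replicate 3 (adjusted p = 0.0393) and with no filter on low values (adjusted p = 0.0116). Vegfa, the main growth factor gene for blood vessels, had 65.6 ± 10.0 normalised reads in DMSO and 60.7 ± 8.31 in GSK libraries, a log2 fold change of -0.11 with a standard error of 0.22 (limma adjusted p = 0.728). Of 23 angiogenic factors 10 fell, among them Wnt7a, Wnt7b, Ntn1 and Angpt2, and 2 rose. The list of angiogenic factors was not called (camera adjusted p = 0.115), though it was called lower without GSK replicate 3 (adjusted p = 0.0466). Tested against no change by fry, hypoxia genes were higher (adjusted p = 0.00177), and angiogenic factors (adjusted p = 0.0308) and genes of mitochondrial dynamics and biogenesis (adjusted p = 0.0285) were lower.

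Genes of cells that follow radial glia in the cortical lineage were higher. Of 17 intermediate progenitor markers 14 rose, 15 when adjusted over the list alone, and none fell (median 0.99, camera adjusted p = 3.25e-06; adjusted p = 0.272 with an estimated correlation). Eomes, the transcription factor gene that defines these cells, rose from 105 ± 26.4 to 250.2 ± 32.4 normalised reads, while Neurog2 did not pass the test (log2 fold change 0.25). Of 30 neuron markers 14 rose, 17 when adjusted over the list alone, and 4 fell (median 0.76, camera adjusted p = 0.00183; adjusted p = 0.622 with an estimated correlation). Tubb3, which encodes a neuronal tubulin, rose from 5964 ± 1844 to 14013 ± 2283 normalised reads, and Elavl3, Nhlh1 and Snap25 rose with log2 fold changes of 1.40, 1.98 and 1.88. Those that fell included Bcl11a, L1cam and Neurod6. Among DMSO libraries, replicate 3 had the lowest Tubb3 value, 4004, and also the lowest globin share. With the globin level of each library as a covariate, chosen after the data were examined, the median of neuron markers became -0.48 (adjusted p = 0.00123). That of Tubb3 became -0.09 (limma adjusted p = 0.961) and that of the 17 intermediate progenitor markers 0.17 (camera adjusted p = 0.205). The median of Cajal-Retzius cell markers became -0.43 (camera adjusted p = 0.734). Of 12 Cajal-Retzius cell markers 7 rose, including Ebf3 and Lhx5, and 2 fell, Ndnf and Calb2 (median 0.86, camera adjusted p = 0.0485; adjusted p = 0.554 with an estimated correlation). The Cajal-Retzius call was lost without DMSO replicate 3 (adjusted p = 0.0557) or GSK replicate 1 (0.176), with median-of-ratios scaling (0.052) and with array weights (0.129), and neuron markers did not pass against no change by fry (0.167). Of 10 Sonic hedgehog targets and ventral forebrain markers 6 rose, including Dlx1, Dlx5 and Gad1, and 2 fell, including Ptch1. This list missed the threshold (camera adjusted p = 0.0501) and passed it when any library but GSK replicate 1 was left out (lowest adjusted p = 0.0221), and with edgeR (0.0205), DESeq2 (0.0303), a pseudocount of 10 (0.0326), TMM scaling (0.0472) or equal library totals (0.0318). Against no change by fry its adjusted p was 0.0066.

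Transcripts of blood cells were much higher in GSK libraries. Of 11 erythroid markers 10 rose and none fell, all 11 rising when adjusted over the list alone (median 4.18, camera adjusted p = 1.91e-07; adjusted p = 0.277 with an estimated correlation). Hbb-y, an embryonic beta globin gene (chromosome 7, 103851749 to 103853216), rose from 6640.2 ± 4838 to 134760 ± 25810 normalised reads, a log2 fold change of 4.78 with a standard error of 0.92 (limma adjusted p = 0.0192). Gata1, the erythroid transcription factor gene, rose from 13.9 ± 4.33 to 144 ± 44.4. Globin genes took 0.173%, 0.234% and 0.0268% of reads in the DMSO libraries and 2.21%, 2.88% and 2.91% in the GSK libraries. Their 95% Wilson intervals, which cover counting error only, ran from 0.0257 to 0.0279% in the lowest library and from 2.90 to 2.93% in the highest. Reads of Hba-a1 cannot be separated with certainty from its near-identical copy. Single globin genes lost their call when a library was left out, with folds of about the same size. The adjusted p of Hbb-y rose to 0.0752 without GSK replicate 2 and 0.0688 without GSK replicate 3, and those of Hbb-bh1, Hba-x and Hba-a1 rose to at most 0.098, 0.103 and 0.0885 without DMSO replicate 1 or any GSK replicate. Without DMSO replicate 3, the library with the lowest globin share, the log2 fold changes fell to 3.86 for Hbb-y, 3.95 for Hbb-bh1 and 3.68 for Hba-x, and all 3 stayed called. Of 15 microglia and macrophage markers 10 rose, 12 when adjusted over the list alone, and none fell (median 3.39, camera adjusted p = 3.02e-06; adjusted p = 0.337 with an estimated correlation). Ptprc, which encodes the leukocyte antigen CD45, rose from 13.8 ± 8.16 to 60.3 ± 2.71 normalised reads, and Lyz2 from 2.59 ± 1.52 to 143 ± 141. Of 17 interferon and innate immune genes 10 rose, including Stat2, Ccl5, Rsad2 and Ifi27 (median 0.83, camera adjusted p = 0.00308; adjusted p = 0.201 with an estimated correlation). The interferon call was lost with a mean of at least 100 (median 0.31, adjusted p = 0.145).

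**Figure D3:**
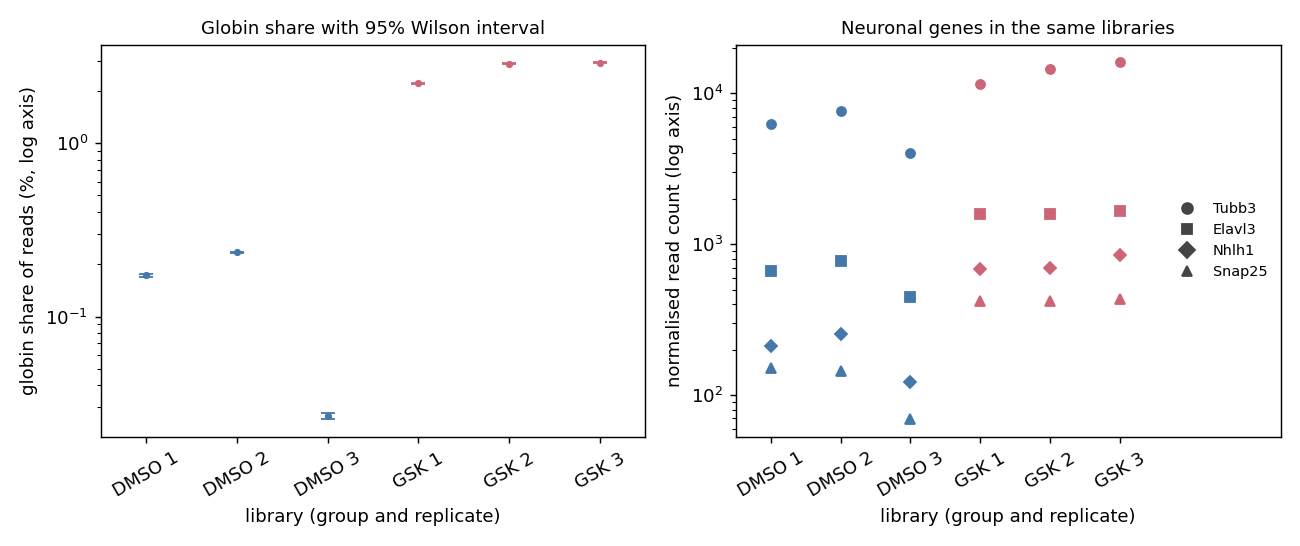
The left panel gives the share of reads from globin genes in each library (percent, log axis, with 95% Wilson intervals), and the right panel gives normalised read counts of 4 neuronal genes (log axis) in the same 6 libraries. DMSO replicate 3 has the lowest globin share, 0.0268%, and the lowest Tubb3 value, 4004.

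Markers of other cell types that the gate could hold differed in direction. No endothelial marker passed the test among 8 (median -0.18, camera adjusted p = 0.491). The smallest p belonged to Kdr and Egfl7, which were lower without passing (limma adjusted p = 0.0544 and 0.0746). Kdr was called lower with edgeR (0.0491), a pseudocount of 10 (0.0455) and equal library totals (0.0415), and Egfl7 with array weights (0.0216). Of 17 pericyte and mesenchyme markers 5 fell, including Acta2, Abcc9 and Col3a1, and 1 rose. Col3a1 lost its call with DESeq2 (adjusted p = 0.0693) and with a total without globin and ribosomal-RNA-overlapping genes (0.0534). The median of 0.03 and the mean of -0.32 differed in sign, and the list was not called (camera adjusted p = 0.413). None of 7 neural crest and glial markers passed (camera adjusted p = 0.849), and of 5 eye field markers only Otx2 did, falling by 0.95 (camera adjusted p = 0.474). The neural crest marker Ngfr (limma adjusted p = 0.0641) was called lower with edgeR (0.0418) and without DMSO replicate 1 (0.0171) or GSK replicate 1 (0.0296). The eye field marker Dct (limma adjusted p = 0.0522) was called lower with a pseudocount of 10 (0.0441), TMM scaling (0.0479), equal library totals (0.039) and without GSK replicate 3 (0.0335). Otx2 lost its call without DMSO replicate 2 (adjusted p = 0.0675) and without GSK replicate 1 (log2 fold change -0.61, adjusted p = 0.0595). Of 5 surface ectoderm and epithelium markers 4 rose, all 5 when adjusted over the list alone, including Tfap2b and Epcam (median 1.05, camera adjusted p = 0.0185; adjusted p = 0.201 with an estimated correlation). With no filter on low values the surface ectoderm call was lost (median 0.18, adjusted p = 0.248), and Epcam lost its call without DMSO replicate 3 (adjusted p = 0.0716). Krt18 lost its call without any 1 DMSO replicate and without GSK replicate 1 (log2 fold change 0.57, adjusted p = 0.286). Tfap2a lost its call without DMSO replicate 1, DMSO replicate 2 or GSK replicate 2 (highest adjusted p = 0.0989).

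The largest rises were taken among called protein coding genes with a mean of at least 100 over all 6 libraries. They included those of Ccl9, Hbb-bh1, Ncf4, Hbb-y, Hba-x, Hba-a1, Spp1, Trib3 and Trim66, with log2 fold changes from 4.29 to 5.10. Some of these genes were low in DMSO libraries, as Ncf4 with a mean of 9.03 and Spp1 with 8.49, and met that limit only through GSK libraries. Ccl9, a chemokine gene, rose from 16.1 ± 23.9 to 281 ± 87.9 normalised reads (limma adjusted p = 0.0375). Its DMSO values were 2.12, 2.58 and 43.7 in replicates 1, 2 and 3, and without DMSO replicate 3 its log2 fold change was 6.35. Without any library but DMSO replicate 3 Ccl9 was no longer called, its adjusted p reaching 0.123. Spp1 was no longer called without DMSO replicate 1, DMSO replicate 2 or GSK replicate 2, its adjusted p reaching 0.0831. Trim66 rose from 14.5 ± 3.46 to 299.6 ± 46.2 normalised reads (limma adjusted p = 4.69e-11). The 10 largest falls were those of Fgf15, Acsbg1, Aqp1, Fabp7, Adamts3, Sorcs1, Slc1a3, H2ac15, H2ac4 and H3c13, with log2 fold changes from -4.82 to -3.10. Acsbg1, an acyl-CoA synthetase gene, fell from 286 ± 45.2 to 18.2 ± 4.66 normalised reads, and the water channel gene Aqp1 from 274 ± 48.7 to 18.6 ± 6.62. H2ac15, H2ac4 and H3c13 encode histones with near-identical copies elsewhere in the genome, so their single values are uncertain. H2ac15 was no longer called without GSK replicate 2 (adjusted p = 0.0881) or GSK replicate 3 (adjusted p = 0.0605).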

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

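The globin covariate, the GC and length correction, the total without ribosomal-RNA-overlapping and globin genes, and the gene by gene array weights were chosen after the data were examined. The count of 5446 changed genes stayed within 1.5 times under the other pseudocounts, filters and scalings, with edgeR (5536 genes) and with DESeq2 (5129 genes, 2 adjusted p missing) on the recovered reads, all of whose values came out whole. Leaving out 1 library gave 4083 to 6298 genes, 1748 to 3071 higher and 2246 to 3227 lower, and 24 to 28 lists. Of 177 named genes that were called, 159 kept their call in all 6 of these fits, as did 22 of 24 lists. Over all settings chosen beforehand, apart from the estimated correlation, 19 of 24 lists kept their call and 5 lost it in some setting: Cajal-Retzius cell markers, FGF and ERK targets, neuron markers (only in the test against no change by fry, adjusted p = 0.167), interferon and innate immune genes (mean of at least 100, 0.145), and surface ectoderm and epithelium markers (no filter on low values, 0.248). With no filter on low values Ccl9 (adjusted p = 0.0808), Hbb-bh1 (0.06), Hba-x (0.0649), Hba-a1 (0.053) and Spp1 (0.0502) were no longer called. An absolute log2 fold change of at least 1 left 1800 genes, 759 higher and 1041 lower, and an adjusted p under 0.01 left 3581, 1562 of them higher, by construction. The planned array weights gave 8962 genes, 4651 of them higher, but the default estimator did not converge. The gene by gene estimator, adopted only after that count was seen, gave 7772 genes, 3963 of them higher; the cause was not tested. The median of cytosolic ribosomal proteins turned to 0.1690 with the planned array weights and 0.1496 without GSK replicate 1, and was -0.1299 without GSK replicate 2; the cause was not tested. With an estimated correlation camera called 0 lists, 0 higher and 0 lower. fry, which tests a list against no change and not against the other genes, passed 28.

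With the globin covariate 428 genes were called, 119 higher and 309 lower, with 10 lists higher. The covariate correlated with the group (r = 0.918 over the 6 libraries), so its effect and that of the inhibitor can hardly be separated. The standard error rose 2.53 times in the median, which alone removes calls. With it 5 lists and 115 named genes lost their call without reversing. Some list medians moved much, as those of erythroid markers (4.18 to 0.0584) and intermediate progenitor markers (0.986 to 0.171). Others moved less: S phase -1.38 to -1.48, radial glial -1.23 to -1.09, ATF4 targets 0.544 to 0.544 and cholesterol synthesis 0.991 to 0.824. Values that changed sign were the median of neuron markers (-0.477), of Cajal-Retzius cell markers (-0.4277), Tubb3 (-0.0859), Hbb-bh1 (-0.168), Hba-x (-0.302), G6pdx (-0.0842) and Bcl2l1 (-0.221). Only the neuron list was called in the new direction (camera adjusted p = 0.00123). The other values did not pass, with adjusted p from 0.734 for Cajal-Retzius cell markers (camera) to 0.961 for Tubb3 (limma). For Hbb-bh1 and Hba-x the covariate is built from the same values; for the others the cause was not tested. The replicate block gave 5642 genes, but ended the calls of Ccl9 (adjusted p = 0.0888), Hbb-bh1 (0.0885), Hbb-y (0.0688), Hba-x (0.0939), Hba-a1 (0.0771) and H2ac15 (0.103). Same-numbered libraries had correlations of 0.0131, -0.0236 and 0.0529 in their deviations from the group means, so the numbers were not read as pairing samples.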

Other observations

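All explanation tests and gene families reported here were chosen after results were seen, including the level of the globin genes and of the marker lists in each library. Families were defined by symbol, 12 in all, and each was tested. Several share genes with the lists above, as minichromosome maintenance genes with the S phase list and kinesins with the G2 and M phase list. Such families are not independent of those lists. Of 48 replication-dependent histone genes 36 were lower and 1, H2bc4, was higher (median -1.92, camera adjusted p = 9.59e-14; adjusted p = 0.154 with an estimated correlation). These messages mostly lack the poly(A) tail that Smart-seq2 needs, and many have near-identical copies. Of 20 nuclear pore genes 16 were lower, led by Nup210 (-1.84) and Nup85 (-1.32), with a median of -0.77 (camera adjusted p = 1.6e-06; adjusted p = 0.0986 with an estimated correlation). Of 9 minichromosome maintenance genes 8 were lower (median -1.38, adjusted p = 2.45e-07; 0.154 with an estimated correlation). Of 39 collagen genes 17 were lower and 3 higher, with Col2a1 at -1.50 and Col18a1 at -2.32 (adjusted p = 0.000772; adjusted p = 0.49 with an estimated correlation). Kinesins were lower in 17 of 34 cases and higher in 6 (adjusted p = 0.00451; adjusted p = 0.404 with an estimated correlation), and mitochondrial ribosomal proteins were lower in 16 of 78 and higher in 2 (adjusted p = 0.025; adjusted p = 0.804 with an estimated correlation). Of all 15073 tested genes 2883 were lower, a similar share to that of the mitochondrial ribosomal proteins.

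All 8 genes of heme synthesis were higher, including Fech (2.46) and Cpox (2.24), with a median of 1.40 (camera adjusted p = 3.75e-06; adjusted p = 0.234 with an estimated correlation). The group includes the erythroid marker Alas2 (3.61), and erythroid markers as a list rose with it (median 4.18). Of 17 subunits of the lysosomal V-type ATPase 12 were higher and none lower (median 0.58, adjusted p = 0.000113; adjusted p = 0.234 with an estimated correlation), and microglia and macrophage markers rose beside them (median 3.39). All 4 distal-less homeobox genes tested, Dlx1, Dlx2, Dlx5 and Dlx6, were higher (median 1.82, adjusted p = 0.00104; adjusted p = 0.188 with an estimated correlation). Proteasome subunits, cytosolic chaperonin subunits and initiation factors were not called (adjusted p = 0.27, 0.279 and 0.308).

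Erythroid and myeloid transcripts were far higher in GSK libraries although the sort selected CD133. RNA of erythroid cells is a candidate explanation for the globins: within groups, erythroid markers followed Hbb-y with a median correlation of 0.979 over the 6 libraries, and of at least 0.933 without any 1 library. Many of these markers are globin genes themselves, so a high value was likely beforehand. Myeloid markers had a median correlation of -0.785, but 0.147 without DMSO replicate 3, so whether they share that source rests on 1 library and stays open. The condition that the value hold without any 1 library was added after -0.785 had been seen, and without it that explanation would have been set aside. Induction of globin genes in progenitors cannot be told apart from erythroid RNA, since bulk libraries do not resolve cells; the ratio of erythroid genes to Hbb-y shifted by -0.791 (log2) in the median. Neuron markers also followed Hbb-y within groups (median correlation 0.917, lowest 0.613 without DMSO replicate 3), a value computed only after the neuron list had reversed under the globin covariate. Intermediate progenitor markers had a median correlation of 0.671 (lowest 0.423 without DMSO replicate 2). A positive correlation with Hbb-y was thus not particular to erythroid markers.

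Radial glial and cell cycle transcripts were lower in GSK libraries. A lower share of progenitors with every other cell type raised alike was compared with the other lists. The lower quartile of erythroid markers lay 3.40 (log2) above the upper quartile of endothelial markers. Both lists had been seen before the comparison was chosen, so its outcome was known and no conclusion is drawn from it. A lower share of progenitors with other cell types raised unequally was not tested. Dilution by RNA of other cells as the whole fall would lower all markers by about the same amount, but 15 of 24 radial glial markers had a 95% interval that excluded the list median, 9 of them above it. After correction for GC content and transcript length the S phase median was -1.37, against -1.38 before. A response of the progenitors to the inhibitor remains a hypothesis, and a change of cell makeup other than such even dilution stays open.

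Integrated stress response transcripts were higher in GSK libraries. Were they brought by the source of the globins, their deviations within groups would follow the predicted mixture with a slope near 1; the slope for the 20 called members was 0.326 with a jackknife standard error of 0.0902, against 1.29 for erythroid markers. The slope lies above 0 by more than 2 standard errors, and the list's 35 tested members had a median correlation with Hbb-y of 0.444 within groups, against 0.0623 over all genes. The 20 members were chosen as called, which favours a small spread within groups and so lowers the slope. The erythroid markers were not chosen so. Hbb-y also varied within groups mainly through DMSO replicate 3, at 1350 against 7729 and 10842 in DMSO replicates 1 and 2. The slope thus cannot decide whether the globin source brought all or part of the rise. After the GC and length correction the list median was 0.568, against 0.544 before. A response of the cells to the inhibitor may account for some or all of the rise, a hypothesis that was not itself tested.

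Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 5446 genes, and the highest of the others gave 0 with limma. Every other split mixes libraries of both groups on each side, so the group difference widens the spread within sides and a low count is built in. The splits are also too few for a share under 0.05, and no conclusion is drawn from them. At an unadjusted p under 0.05, the real split gave 6763 genes.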
